A study of Mus musculus with 5 samples.

How the data were processed

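Gene expression was measured in single cells from mouse hearts, after cells carrying CD45, a surface protein of blood-derived cells, had been enriched with magnetic beads. Droplet libraries that tag the 3′ ends of transcripts with unique molecular identifiers (UMIs) were made with version 2 reagents of 10x Genomics, per the labels' protocols, with a recovery target of 10000 cells. The labels put 5 libraries in 3 groups. Sham is 1 library from sham-operated mice with both copies of Pcsk9. MI is 2 libraries from LAD-operated mice of the same genotype, and MIKO is 2 libraries from LAD-operated mice lacking Pcsk9. The time between surgery and collection is not given in the sources used here. The protocol calls all hearts infarcted, the sham-operated included. The labels do not say that the replicates of a group are separate animals, so p-values measure the spread between these libraries, which may be technical.

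The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger. The version was 5.0.0 for 4 libraries and 6.0.1 for MIKO replicate 1, per the file headers. The submitters' processing notes name mm10 as the genome build, and also Seurat, for which no step is given in the sources used here. All deposited barcodes hold at least 500 UMIs. Gene positions were taken from the GENCODE annotation of GRCm38, the same build as mm10.

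The 62009 barcodes and 32285 genes were read with Python 3.11.15 and scanpy 1.11.5. Barcodes were kept with at least 200 genes, at least 500 UMIs, under 10% mitochondrial UMIs and at most the 99.9th percentile of UMIs of their library. Doublets were scored with Scrublet in each library. Its automatic threshold marked between 0 and 0.0105% of barcodes, which was taken as a failure. The fallback fixed in advance was then used, which removes the barcodes with the highest scores, at an expected share of 0.8% per 1000 barcodes. It marked 13.8% of the Sham barcodes, 7.95% and 10.9% in MI and 9.90% and 10.3% in MIKO.

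The 54076 remaining cells were scaled to 10000 counts, log-transformed and clustered together without integration. This step used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. Mitochondrial, ribosomal, haemoglobin and sex-linked genes, Pcsk9 and its neighbours on the chromosome were left out of the variable genes. Of the 36 clusters, 26 were merged into classes named from markers fixed before the data were examined, written as "X-like". A name needed at least 3 markers detected in 20% of cells and raised to over 2 times the median cluster, at least 2 markers among the 50 leading genes, and no second class with a score of 0.75 of the first or more. The score counts markers raised or leading, relative to the length of each marker list, so a class with a long list can have more markers raised and still rank second, as monocyte/macrophage markers did in the mural-like cluster 26. A cluster also stayed unnamed if at least 0.4 of the markers of another class were raised, stromal classes counting as 1. The same held if its 10 leading genes held more markers of another class. It held too for few UMIs with no marker among those 10. Clusters 28 and 34 were left out for markers of 2 classes, and cluster 29 for leading genes of another class. The requirement on the 50 leading genes was set after seeing the data. It kept clusters 8, 11, 15 and 36 out of any class. Cluster 8 made up 0.963% of Sham cells, 4.75% and 3.51% of MI cells and 0.495% and 9.92% of MIKO cells. Cluster 11 made up 1.36%, then 2.63% and 4.73%, then 5.37% and 2.41%. Cluster 15, led by genes of dividing cells such as Top2a and Mki67, made up 2.28%, then 2.25% and 3.04%, then 2.90% and 2.26%. Cluster 36 made up 0.287% of MI replicate 2, 0.0101% of MIKO replicate 1 and no cell of the other libraries. In all, 10 clusters with 6215 cells stayed unnamed. Library depth after these steps ran from 61911555 to 76690907 UMIs.

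UMI counts were summed over the cells of a class in each library, with at least 20 cells per library. The sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 5 libraries, with filterByExpr, TMM factors and Benjamini-Hochberg adjustment at 0.05. The fit leaves 2 residual degrees of freedom. The single Sham library adds none and was assumed to vary like the others. Numbers of cells per class were tested with the same model, with total cells as library size. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 1 in 3, so none is reported. Levels are given as CPM, a gene's UMIs scaled to the total of its class in a library. Means are followed by the SD over the 2 libraries of a group. The 2 libraries of MI and of MIKO were compared before averaging in the 4 classes tested for genes. In each they differed by more than independent draws of UMIs would give. UMIs come grouped in cells, and the sampling of cells was not taken into account.

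Before the data were examined, 43 gene lists were fixed. Lists with at least 4 tested genes were compared with camera (limma 3.58.1) at a preset correlation of 0.01. They were tested again with a correlation estimated from the data and with fry, which asks whether a list's genes move at all and not whether they move more than other genes. In simulated counts a list raised by 1.5 times in monocyte/macrophage-like cells, MIKO against MI, was called with the preset correlation and not with the estimated one or fry. This was a single list with genes drawn independently. It does not measure how often either setting misses or wrongly calls lists whose genes move together. The lists described in detail and the genes drawn in the plots were picked after the results were seen, and the list tests of MI against Sham in neutrophil-like cells were not planned.

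The genes named were chosen by a rule fixed in advance. In monocyte/macrophage-like and neutrophil-like cells these were the 10 largest changes in each direction among genes past the adjusted threshold, with a mean of at least 20 CPM and no overlap between the libraries of the groups. In T cell-like and B cell-like cells 3 per direction were taken. Predicted genes, variable segments, mitochondrial, ribosomal and haemoglobin genes and markers of other classes were left out. Pcsk9, Ldlr, Xist and up to 4 members of each described list with the smallest p were added. Where no gene passed, 3 per direction with the smallest p are given as values.

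The tests were checked on simulated counts with 200 changed genes. Each gene was drawn independently at the trend of the spread, without a scatter of its own. Genes with few counts were never among those changed. The shares recovered can therefore lie above those reached in the data. For MIKO against MI, edgeR recovered 80% of genes changed by 2 times and 98% of those changed by 4 times in monocyte/macrophage-like cells, among 13752 genes. In neutrophil-like cells it recovered 33% and 83%, in T cell-like cells 28% and 94%, and in B cell-like cells 30% and 97%. For MI against Sham the shares were 73% and 85.7% in monocyte/macrophage-like cells, 17% and 75% in neutrophil-like cells, 29% and 84% in T cell-like cells and 25% and 84% in B cell-like cells. Of the genes called by edgeR in these simulations for MIKO against MI, 10 of 188 were false in monocyte/macrophage-like cells, 5 of 121 in neutrophil-like cells, 11 of 133 in T cell-like cells and 4 of 131 in B cell-like cells. For MI against Sham 5 of 162, 2 of 94, 1 of 114 and 8 of 117 were false. The false share thus passed 0.05 in some sets, the most in T cell-like cells. In a simulated change of 4 times in the NK cell-like share, the share test called that class alone and estimated 5.64 times.

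Alternatives fixed in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, and stricter cells (at least 1000 UMIs and under 5% mitochondrial). Others were doublets kept, Leiden resolution 2.0 (49 clusters), equal cell numbers per library and each MI or MIKO library left out in turn. At resolution 2.0 the clusters were named anew, so the make-up of a class can differ from the main setting. For shares, limma on the logit scale, TMM factors and shares without stromal classes were added. A crossed pairing of the replicate numbers was added after seeing the data. Other tools used were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Intervals are exact binomial at 95%, and limits for a count of 0 use 3 counts. Both cover counting error only.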

Results

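Immune cells of the heart were profiled after a sham operation or LAD surgery in mice with and without Pcsk9. The libraries held 16924 barcodes for Sham, 9613 and 12242 for MI, and 11225 and 12005 for MIKO. Their total counts lay between 74859920 and 89554886 UMIs, with medians of 3329 UMIs per barcode in Sham, 4378 and 3692 in MI and 4070 and 3459 in MIKO. After filtering, 14021 Sham cells, 8745 and 10783 MI cells and 9891 and 10636 MIKO cells were compared. In each class tested the 2 libraries of a group differed by more than independent draws of UMIs give, the sampling of cells aside. Their chi-square per degree of freedom ran from 2.30 between MIKO T cell-like sums to 44.4 between MIKO monocyte/macrophage-like sums. Sham had no replicate, so each comparison with it borrows the spread of the other 2 groups.

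Pcsk9 encodes a secreted protein that sends the LDL receptor to degradation and is made mainly in the liver. The gene (ENSMUSG00000044254) lies on chromosome 4 from 106442329 to 106464329 in mm10. Over all barcodes it had 1 UMI in MI replicate 2, or 0.0134 CPM of the whole library, and none in the other 4 libraries, where a count of 0 allows up to 0.0335 to 0.0394 CPM. No UMI remained among the cells compared. A single UMI in 1 of the 3 wild-type libraries is too little to check any of the genotype labels, and the deleted part of the gene is not given in the sources used here. The genes flanking Pcsk9, as a list, were not called by camera between MIKO and MI in monocyte/macrophage-like cells (adjusted p = 0.961) or neutrophil-like cells (adjusted p = 0.868). Ldlr, the receptor that PCSK9 targets, stood at 23.9 ± 2.84 CPM in MI and 32.7 ± 5.54 CPM in MIKO monocyte/macrophage-like cells (SD, n = 2), with 37.6 CPM in Sham. The log2 difference of 0.36 (SE 0.16) between MIKO and MI did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.529). In neutrophil-like cells Ldlr was at 10.55 CPM in Sham and 2.59 ± 1.26 CPM in MI (SD, n = 2), a log2 difference of -2.04 that did not pass the same edgeR test (adjusted p = 0.0779). Xist, transcribed from the inactive X chromosome, had 2 UMIs in MIKO replicate 2 and none in the other 4 libraries in monocyte/macrophage-like cells. Y-linked genes summed to between 80.0 and 99.98 CPM there, so each library held RNA of male cells.

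The first comparison asked which cells the heart held after LAD surgery. Neutrophil-like cells, the first blood cells to enter injured tissue, made up 9.74% of Sham cells (95% exact interval 9.25 to 10.2) and 32.2 ± 7.03% of MI cells (SD, n = 2). Intervals of the single Sham library cover counting error only. Lymphocytes were scarcer in MI: B cell-like cells went from 12.6% (12.02 to 13.1) to 3.73 ± 0.941%, T cell-like cells from 4.69% (4.34 to 5.05) to 1.62 ± 0.535% and NK cell-like cells from 4.34% (4.01 to 4.69) to 1.04 ± 0.318%. Fibroblast-like cells went from 8.77% (8.31 to 9.25) to 0.646 ± 0.153%, mural-like cells of the vessel wall from 7.28% (6.86 to 7.72) to 0.691 ± 0.217% and endothelial-like cells from 3.14% (2.86 to 3.44) to 0.809 ± 0.0762%. Of the mural-like cells, cluster 26 (Rgs5, Myh11), in which 3 mural and 10 monocyte/macrophage markers were raised, made up 4.12% of Sham and under 0.08% of every other library, so over 0.5 of the Sham level lay in a cluster nearly absent elsewhere. Cluster 25 (Tagln, Acta2) held 3.16% of Sham and 0.503% and 0.807% of MI. The CD45 selection should remove these 3 stromal classes, so their shares depend on how well it worked in each preparation. Monocyte/macrophage-like cells were the largest class, with 37.5% (36.7 to 38.3) in Sham and 46.5 ± 2.69% in MI. In edgeR's quasi-likelihood test on cell numbers, with Benjamini-Hochberg adjustment over 10 classes, 7 shares changed. The neutrophil-like share rose (log2 1.73, adjusted p = 0.00989). The shares of fibroblast-like (-3.76, 5.72e-06), mural-like (-3.39, 1.12e-05), NK cell-like (-2.06, 0.00211), endothelial-like (-1.95, 0.00279), B cell-like (-1.75, 0.00448) and T cell-like cells (-1.52, 0.00989) fell. The shares of dendritic cell-like (adjusted p = 0.153), monocyte/macrophage-like (0.562) and unnamed cells (0.548) did not pass. Without MI replicate 1 edgeR called 0 shares, with 4 at an unadjusted p under 0.05, and without MI replicate 2 it called 2. With all libraries, limma on the logit of the shares called 7. TMM factors over the classes, which scale the libraries to one another in place of using total cells, gave 3 higher and 2 lower shares in place of 1 higher and 6 lower. With them edgeR called the neutrophil-like (log2 3.04, adjusted p = 0.0140) and monocyte/macrophage-like shares higher (1.61, 0.0174) and the fibroblast-like (-2.46, 0.0174) and mural-like shares lower (-2.11, 0.0182). The falls of the B cell-like (-0.46, 0.296), NK cell-like (-0.78, 0.178), T cell-like (-0.24, 0.577) and endothelial-like shares (-0.66, 0.415) were smaller and did not pass. Among non-stromal cells alone edgeR called 5 shares: neutrophil-like cells were higher (1.45, 0.00769), and B cell-like (-2.03, 0.000439), NK cell-like (-2.33, 0.000297), T cell-like (-1.80, 0.00104) and also dendritic cell-like cells were lower (-1.10, 0.0212).

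The second comparison asked what loss of Pcsk9 altered after LAD surgery. NK cell-like cells made up 1.04 ± 0.318% of MI and 0.402 ± 0.0965% of MIKO cells, and fibroblast-like cells 0.646 ± 0.153% and 1.88 ± 0.778% (SD, n = 2). The NK cell-like share fell (log2 -1.37, SE 0.47, adjusted p = 0.0413) and the fibroblast-like share rose (log2 1.54, SE 0.45, adjusted p = 0.0292) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both MIKO libraries lay beyond both MI libraries in each case. The fibroblast-like cells of cluster 27, led by Col1a1 and Postn, made up 2.08% and 0.480% of the MIKO libraries and 0.377% and 0.213% of the MI libraries. The fibroblast-like cells of cluster 16, led by Dcn and Clec3b, made up 0.344% and 0.846% of the MIKO libraries and 0.377% and 0.325% of the MI libraries, so most of the rise lay in cluster 27 in MIKO replicate 1 and in cluster 16 in MIKO replicate 2. Neutrophil-like cells stood at 32.2 ± 7.03% in MI and 31.5 ± 0.456% in MIKO, and monocyte/macrophage-like cells at 46.5 ± 2.69% and 42.02 ± 2.09%. Neither passed (adjusted p = 0.944 and 0.816 in the same edgeR test). Limma called the same number of shares, 2. The NK cell-like call was lost with doublets kept (log2 -1.27, edgeR adjusted p = 0.0563) and with the replicate number as a block (log2 -1.35, edgeR adjusted p = 0.0502). The fibroblast-like call stayed in both. With edgeR, no share was called without MI replicate 1, MI replicate 2 or MIKO replicate 1 (1, 0 and 0 at an unadjusted p under 0.05), 1 without MIKO replicate 2, and 0 with stricter cells, with TMM factors or at the finer clustering (2, 2 and 3 at an unadjusted p under 0.05).

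**Figure D1:**
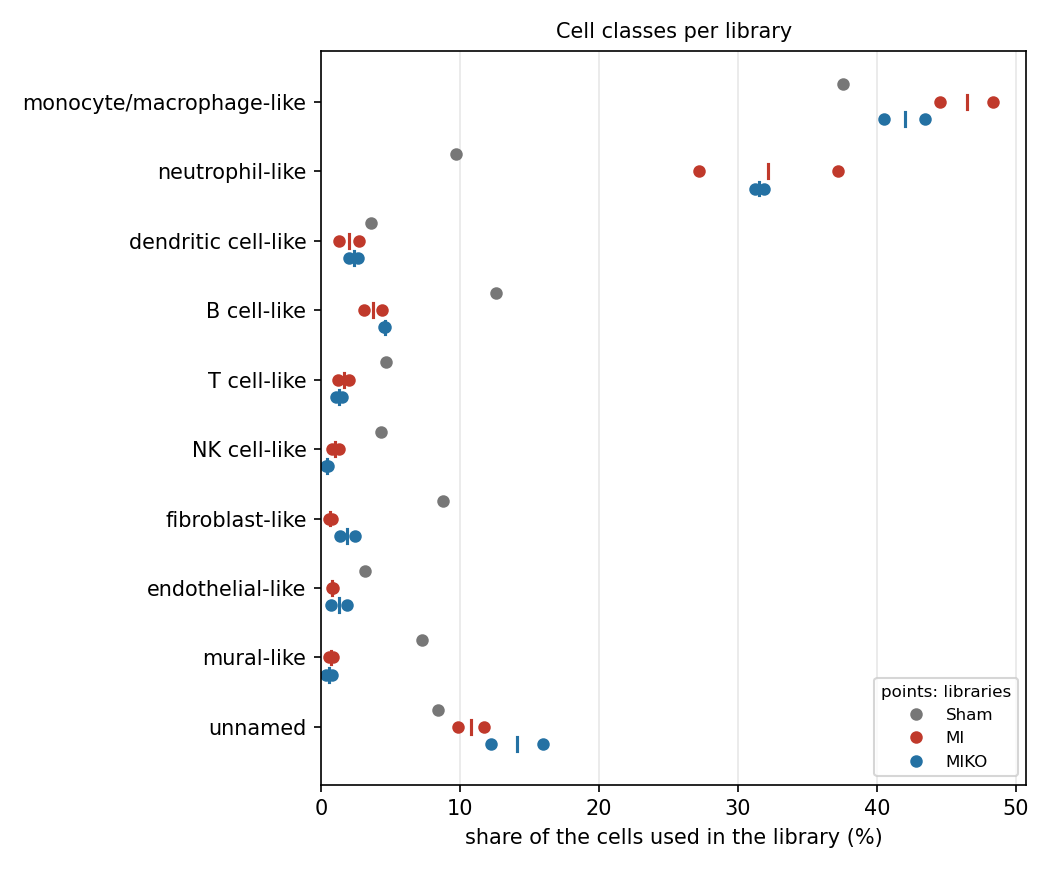
Share of each cell class in each library, as a percent of the cells compared, with 1 point per library and a tick at the mean of the 2 MI and the 2 MIKO libraries. Neutrophil-like cells lay at 9.74% in Sham and averaged 32.2% in MI and 31.5% in MIKO.

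In monocyte/macrophage-like cells, LAD surgery went with higher RNA of single genes that attract other leukocytes, answer to hypoxia or break down haem and arginine. Cxcl3, which attracts neutrophils, rose from 129 CPM in Sham to 968 ± 48.4 CPM in MI, and Ccl7, which attracts monocytes, from 584 to 2829 ± 542 CPM (SD, n = 2). Arg1, the arginase of repair macrophages, rose from 366 to 1715 ± 17.0 CPM, Hmox1, which breaks down haem, from 906 to 3186 ± 706 CPM, and Hilpda, a lipid-droplet protein induced by hypoxia, from 161 to 597 ± 32.4 CPM. The other genes among the 10 largest rises were Inhba (log2 2.64), a subunit of activin, the interferon-inducible Slfn4 (2.24), Ly6a (2.14), Flrt3 (2.14) and Serpine1 (2.10), the inhibitor of plasminogen activation. Genes typical of macrophages resident in the healthy heart fell: Lyve1, a hyaluronan receptor, went from 91.8 to 6.07 ± 0.856 CPM, Cd163, the receptor for haemoglobin bound to haptoglobin, from 52.4 to 10.8 ± 2.74 CPM, and Hpgd, which degrades prostaglandins, from 137 to 11.5 ± 1.41 CPM. The other large falls were in the lectin Mgl2 (log2 -3.28), the heat-shock gene Hspb1 (-2.60), the MHC class II genes H2-Eb1 (-2.25) and H2-Ab1 (-1.98), the tetraspanin gene Cd81 (-2.21), and Tmem176b (-2.06) and Tmem176a (-1.97). The class was made up of several clusters in each group. Cluster 10, led by MHC class II genes such as H2-Aa, held 4.05% of all Sham cells and 3.28% and 4.63% of the MI libraries. Cluster 3 (Ly6c2, Plac8) held 10.2% of all Sham cells and 6.56% and 7.61% of the MI libraries, and the resident clusters 13 and 18 held 7.41% and 5.23% of Sham and under 1% of each MI library. Cluster 2 (Gpnmb, Spp1) held 3.77% of Sham and 13.6% and 14.3% of MI, cluster 5 (Inhba, Cxcl3) 1.78% and then 7.71% and 6.52%, and cluster 7 (Trem2, Lpl) 2.71% and then 5.45% and 7.39%.

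Over 14252 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1279, of which 527 rose and 752 fell in MI. Adjusted p was 0.00189 for Cxcl3 (log2 3.08, SE 0.21), 0.00543 for Arg1 (2.40, 0.23), 0.000348 for Hpgd (-3.41, 0.13) and 0.00359 for Lyve1 (-3.75, 0.30) in this edgeR fit. The count depended on single libraries: it was 52 without MI replicate 1, 334 without MI replicate 2, 2394 without MIKO replicate 1 and 2417 without MIKO replicate 2. With no filter on low counts it was 385.

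Among the gene lists, camera with a preset correlation called 23 of 43 in these cells, 11 higher and 12 lower in MI. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05, lowest adjusted p = 0.376), fry called 0 for direction (15 at an unadjusted p under 0.05) and 29 for change either way. Glycolysis and hypoxia genes were higher with a median log2 difference of 0.70 (camera adjusted p = 1.12e-13; adjusted p = 0.376 with an estimated correlation). Of its 29 genes 16 rose, or 21 adjusted over the list alone with 1 lower, and Bnip3 (1.64), Mif (1.46) and the glycolytic enzyme gene Pgk1 (1.07) were among them. Nuclear genes of oxidative phosphorylation had a median of 0.46 (camera adjusted p = 1.12e-13; adjusted p = 0.558 with an estimated correlation), with 12 of 55 rising and 33 adjusted over the list alone. Ndufc1 (0.86) and Cox7b (0.67), subunits of respiratory complexes, were examples. Chemokine genes had a median of 0.73 (camera adjusted p = 5.97e-07; adjusted p = 0.376 with an estimated correlation). Of 21, 10 rose and 1 fell, or 13 and 2 adjusted over the list alone; Ppbp rose (2.40) and Cxcl13, which attracts B cells, fell (-3.55). Genes of Trem2/Spp1 macrophages, which handle lipids and debris, had a median of 0.44 (camera adjusted p = 3.23e-05; adjusted p = 0.376 with an estimated correlation). Of 18, 6 rose, or 7 adjusted over the list alone, among them Spp1 (1.51), Ctsl (1.04) and the fatty acid carriers Fabp5 (0.94) and Fabp4 (0.70).

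Lists that were lower in MI included resident macrophage genes, with a median log2 difference of -1.38 (camera adjusted p = 2.24e-08; adjusted p = 0.558 with an estimated correlation). Of these 20 genes 12 fell, and the same count passed adjusted over the list alone, with Timd4 (-3.57), a receptor for dying cells, and Klf2 (-1.90) beside Lyve1 and Hpgd. MHC class II genes had a median of -1.91 (camera adjusted p = 3.95e-08; adjusted p = 0.558 with an estimated correlation), and 11 of 12 fell over all genes and adjusted over the list alone, including their regulator Ciita (-2.02) and H2-Aa (-1.97). Cholesterol synthesis genes, targets of SREBP2, had a median of -0.35 (camera adjusted p = 0.000122; adjusted p = 0.376 with an estimated correlation). Of 25, 5 fell, or 6 adjusted over the list alone, among them Cyp51 (-0.78), Idi1 (-0.73), Stard4 (-1.003) and Dhcr24 (-0.997). RNA of other cells moved the same way: 10 of 10 B cell markers fell in these monocyte/macrophage-like sums (median -2.65, camera adjusted p = 2.97e-10; adjusted p = 0.376 with an estimated correlation; 10 also adjusted over the list alone). Cardiomyocyte genes had a median of -2.36 (camera adjusted p = 2.07e-08; adjusted p = 0.558 with an estimated correlation), with 9 of 15 falling and 13 adjusted over the list alone.

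**Figure D2:**
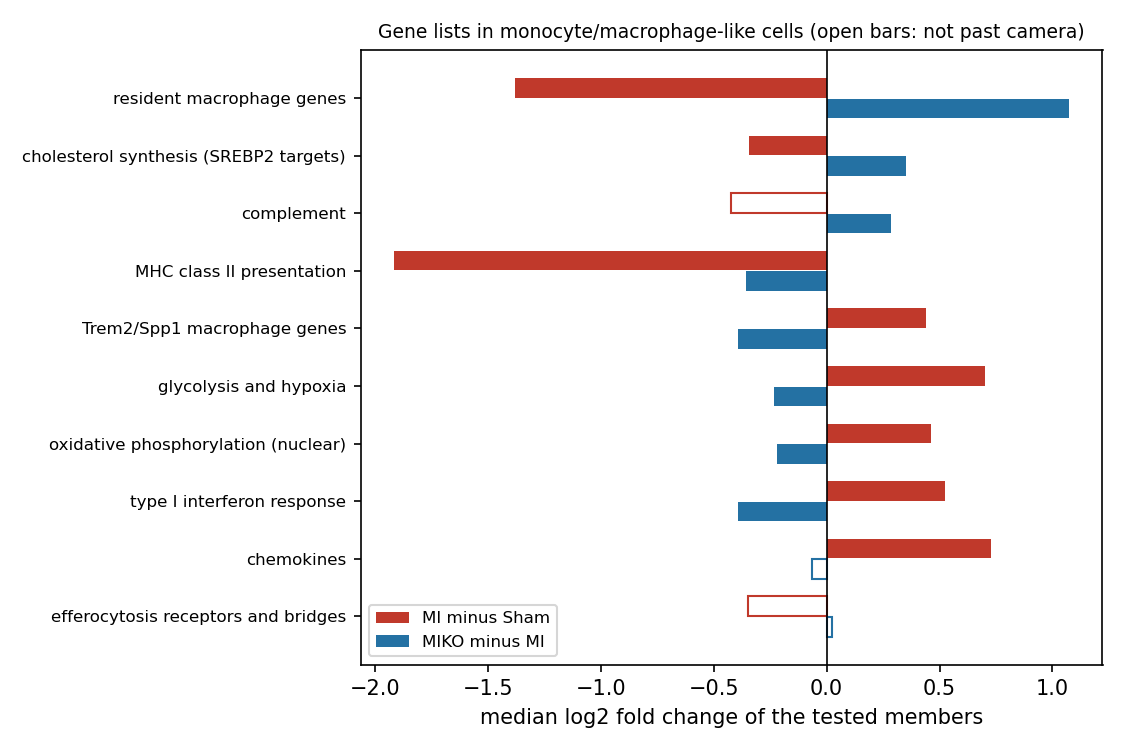
Median log2 difference of each plotted gene list in monocyte/macrophage-like cells, MI against Sham and MIKO against MI, with open bars where camera made no call. In monocyte/macrophage-like cells the resident macrophage list stood at -1.38 for MI against Sham and at 1.07 for MIKO against MI.

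Neutrophil-like cells of MI hearts carried far more RNA of inflammatory cytokines than those of the Sham heart. Tnf rose from 139 CPM in Sham to 2327 ± 282 CPM in MI, Il1a from 23.5 to 919 ± 297 CPM, and Il23a, a subunit of the cytokine IL-23, from 20.4 to 439 ± 30.4 CPM (SD, n = 2). The chemokine genes Cxcl3 (log2 3.62) and Ccl3 (3.79), the granulocyte growth factor gene Csf3 (4.32), the cystatin gene Csta2 (4.26), Fmnl2 (4.11), the kinase gene Ikbke (3.78) and the fatty acid receptor gene Gpr84 (3.66) completed the 10 largest rises. Among the falls, Camp, the antimicrobial peptide cathelicidin, went from 388 to 6.84 ± 5.02 CPM and Ltf, lactoferrin, from 310.0 to 18.4 ± 6.89 CPM. Prok2, a secreted chemoattractant, went from 400.2 to 11.2 ± 1.46 CPM, and the surface marker Ly6g from 1003 to 69.6 ± 7.66 CPM. The collagenase gene Mmp8 (-2.86), Ggt1 (-3.15), Adpgk (-3.04), Mov10 (-2.99), Aldh2 (-2.82) and Gyg (-2.58), which primes glycogen synthesis, also fell. In Sham most of the class came from cluster 4 (4.55% of all cells; S100a9, G0s2) and cluster 20 (4.21%; Ngp, Camp, Ltf). In MI most came from cluster 1 (10.3% and 10.6%; Il23a, Icam1, Tnf), cluster 14 (10.1% and 4.66%; Stfa1, Lcn2), cluster 4 (8.005% and 9.36%) and cluster 12 (8.45% and 2.46%; Ifit1, Rsad2).

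In this class edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 304 of 11014 genes, 154 higher and 150 lower in MI, with adjusted p = 0.00471 for Il23a (log2 4.47, SE 0.27), 0.0146 for Il1a (5.34, 0.45) and 0.00343 for Prok2 (-5.12, 0.25). The count was 643 without MI replicate 2, 486 without MIKO replicate 1, 1589 with no filter on low counts and 614 with DESeq2. Inflammatory cytokine genes driven by NF-kB had a median log2 difference of 1.85 (camera adjusted p = 7.35e-22; adjusted p = 0.457 with an estimated correlation). Of 25, 16 rose, or 23 adjusted over the list alone with 1 lower, including Icam1 (3.33) and Ptgs2 (2.14). Genes of tissue-activated neutrophils had a median of 2.13 (camera adjusted p = 1.34e-19; adjusted p = 0.457 with an estimated correlation), with 16 of 24 rising and 19 adjusted over the list alone. Neutrophil granule genes had a median of -1.01 (camera adjusted p = 3.79e-08; adjusted p = 0.457 with an estimated correlation). Of 24, 7 fell, or 16 lower and 2 higher adjusted over the list alone, with Padi4 (-2.14) and Anxa1 (-1.84) among them. Summed haemoglobin RNA in these cells, a measure of blood carried along, was 180 CPM in Sham and 2.60 and 3.66 CPM in the MI libraries.

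In MIKO against MI, monocyte/macrophage-like cells carried more RNA of Lyve1, Cd163 and Timd4, the 3 of 20 resident macrophage genes that passed. Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239) rose from 6.07 ± 0.856 CPM in MI to 65.2 ± 27.8 CPM in MIKO (SD, n = 2), with 91.8 CPM in Sham. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) rose from 10.8 ± 2.74 to 77.5 ± 27.3 CPM, with 52.4 CPM in Sham. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase protein gene, rose from 253 ± 25.9 to 819 ± 185 CPM, with 277 CPM in Sham. Lifr (ENSMUSG00000054263, chromosome 15, 7090614 to 7197489), the receptor for leukaemia inhibitory factor, rose from 11.9 ± 0.0241 to 29.9 ± 0.952 CPM, with 45.4 CPM in Sham. The remaining genes called lay outside the naming rule and were named after their values were seen. They were Timd4 (log2 2.19), the calcium-binding alarmin S100a8 (1.85), Fxyd2 (1.80), the adhesion molecule gene Vcam1 (1.53) and Lilra5 (1.23), which rose, and the proton pump subunit gene Atp6v0d2 (-1.18), which fell. S100a8 is a marker of neutrophils and stood at 158 ± 8.30 CPM in MI and 615 ± 174 CPM in MIKO. The resident clusters 13 and 18 held 0.515% and 0.617% of MI replicate 1, 0.529% and 0.862% of MI replicate 2, 2.66% and 1.57% of MIKO replicate 1 and 2.06% and 1.21% of MIKO replicate 2. Cluster 24 of this class, with Saa3 among its leading genes, held 1.21% and 0.640% of the MI libraries and 2.62% and 0.743% of the MIKO libraries. RNA of heart muscle moved with the groups too: the cardiomyocyte list summed to 55.8 and 66.5 CPM in MI and 172 and 78.3 CPM in MIKO.

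Of 14252 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10, 9 higher and 1 lower in MIKO. Adjusted p was 0.0414 for Lyve1 (log2 3.31, SE 0.28), 0.0446 for Cd163 (2.74, 0.25), 0.0484 for Saa3 (1.58, 0.16) and 0.0414 for Lifr (1.22, 0.10) in this edgeR fit. These calls lay close to the threshold. With edgeR, 0 genes passed without MI replicate 1, without MI replicate 2, with doublets kept or with no filter on low counts (1294, 978, 1394 and 1376 at an unadjusted p under 0.05). The count was 153 with DESeq2, 37 at the finer clustering and 6 with stricter cells. At the finer clustering a cluster of 2971 cells led by Cxcl3, Areg, Ppbp and Arg1 stayed unnamed. It had 16 monocyte/macrophage markers raised, but its 10 leading genes held more markers of another class. The monocyte/macrophage-like class then held 3126 and 4048 MI cells and 3077 and 3572 MIKO cells, against 3896, 5214, 4302 and 4312. The 37 genes thus come from a class of another make-up. The 10 genes first called had the same direction under all of these settings and with either MIKO library left out.

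**Figure D3:**
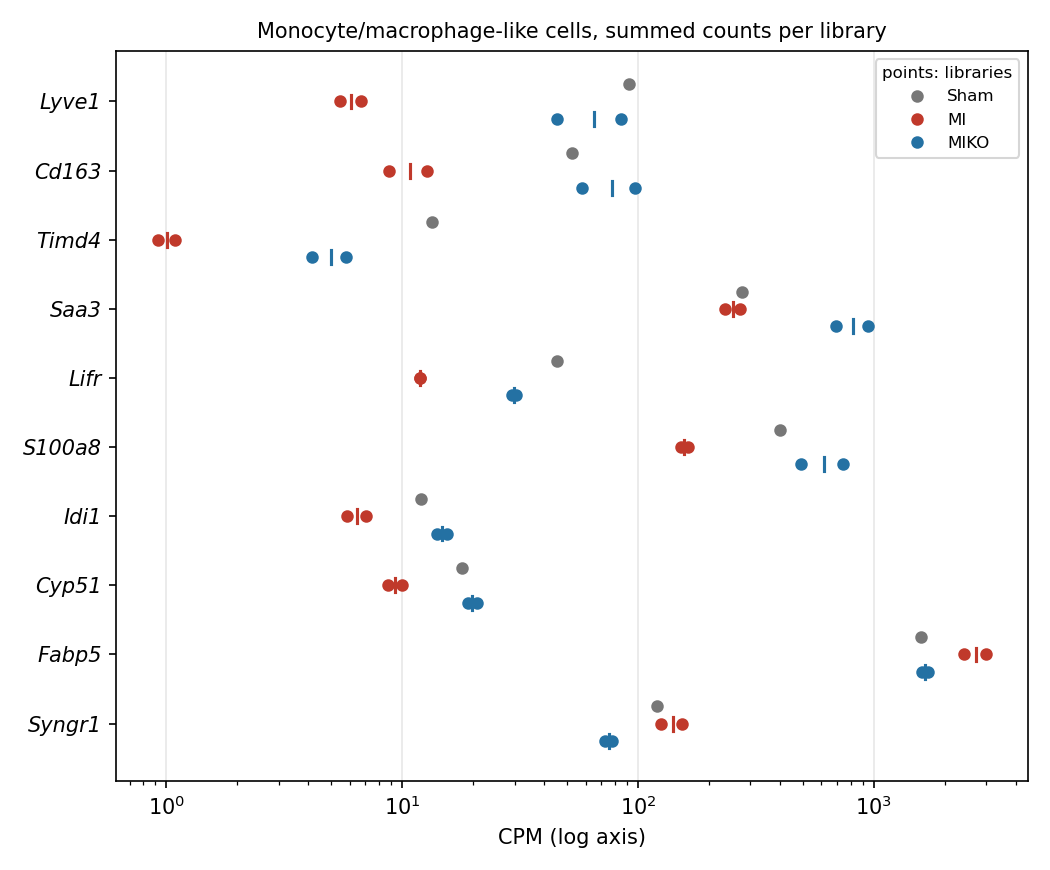
CPM of selected genes in monocyte/macrophage-like cells on a log axis, with 1 point per library and a tick at the mean of the 2 MI and the 2 MIKO libraries. Lyve1 averaged 6.07 CPM in MI and 65.2 CPM in MIKO and lay at 91.8 CPM in Sham.

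Camera with a preset correlation called 19 of the 43 lists in MIKO against MI monocyte/macrophage-like cells, 8 higher and 11 lower. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05), and fry called 0 for direction (7 at an unadjusted p under 0.05) and 14 for change either way. Resident macrophage genes had a median log2 difference of 1.07 (camera adjusted p = 2.09e-15; adjusted p = 0.455 with an estimated correlation). Of 20, 3 rose (Lyve1, Cd163 and Timd4), or 12 adjusted over the list alone, and Hpgd had a log2 difference of 0.91. Cholesterol synthesis genes had a median of 0.35 (camera adjusted p = 8.52e-12; adjusted p = 0.319 with an estimated correlation). None of the 25 passed over all genes with edgeR, and 10 rose adjusted over the list alone, with Idi1 at 1.09, Cyp51 at 0.99, Dhcr24 at 1.42 and Sqle at 0.86. At a level of 9.34 ± 0.929 CPM in MI and 19.9 ± 1.18 CPM in MIKO (SD, n = 2), Cyp51, which removes a methyl group from lanosterol, lay near the 17.96 CPM of Sham. Complement genes had a median of 0.29 (camera adjusted p = 1.06e-05; adjusted p = 0.319 with an estimated correlation), with none of 19 past the test over all genes and 4 higher and 1 lower adjusted over the list alone. Vsig4, a complement receptor of tissue macrophages, differed by 2.81, C4b by 0.88 and Cfh by 0.82. Neutrophil markers had a median of 0.37 (camera adjusted p = 0.00515; adjusted p = 0.455 with an estimated correlation), with S100a8 the 1 of 10 that rose over all genes and 3 adjusted over the list alone. This call was lost with doublets kept (camera adjusted p = 0.0777) and at the finer clustering (0.113). S100a9 had a log2 difference of 2.35 and did not pass (edgeR adjusted p = 0.0616). Cardiomyocyte genes had a median of 1.67 (camera adjusted p = 9.82e-11; adjusted p = 0.508 with an estimated correlation), with none of 15 past the edgeR test over all genes and 13 higher adjusted over the list alone.

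Lower in MIKO were genes of Trem2/Spp1 macrophages, with a median log2 difference of -0.39 (camera adjusted p = 6.91e-10; adjusted p = 0.319 with an estimated correlation). None of the 18 passed over all genes and 8 fell adjusted over the list alone, with Syngr1 at -1.003, Lpl, a lipase of triglyceride particles, at -0.98, Fabp5 at -0.82 and Fabp4 at -0.81. The shares of the clusters led by such genes did not all fall. Cluster 2 (Gpnmb, Spp1) held 13.6% and 14.3% of the MI libraries and 16.4% and 12.8% of the MIKO libraries. Cluster 7 (Trem2, Lpl) held 5.45% and 7.39%, then 5.02% and 3.77%. Type I interferon response genes had a median of -0.39 (camera adjusted p = 1.03e-15; adjusted p = 0.508 with an estimated correlation), with none of 38 past the test over all genes and 9 lower adjusted over the list alone. Ifit3b (-0.95) and Cmpk2 (-0.60) had the smallest p among them. The interferon-led cluster 9 (Rsad2, Cxcl10) held 5.61% and 5.90% of the MI libraries and 2.27% and 3.98% of the MIKO libraries. Glycolysis and hypoxia genes had a median of -0.23 (camera adjusted p = 1.38e-09; adjusted p = 0.319 with an estimated correlation). None of 29 passed over all genes and 3 fell adjusted over the list alone, with Egln3, an oxygen sensor, at -1.35, Ankrd37 at -0.85 and Bnip3 at -0.61. Receptors and bridging proteins for the uptake of dying cells had a median of 0.02 and were not called (camera adjusted p = 0.141; adjusted p = 0.508 with an estimated correlation). Of 23, Timd4 alone rose over all genes, and 3 rose and 1 fell adjusted over the list alone, with Gas6 at 0.69, Stab1 at 0.52 and Axl at -0.63.

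In neutrophil-like cells, Prok2 (ENSMUSG00000030069, chromosome 6, 99711299 to 99726392) rose from 11.2 ± 1.46 CPM in MI to 175 ± 31.0 CPM in MIKO (SD, n = 2), with 400.2 CPM in Sham. The granule genes Camp (6.84 ± 5.02 CPM in MI and 318 ± 232 CPM in MIKO) and Ltf (18.4 ± 6.89 and 371 ± 180 CPM) had large log2 differences of 5.28 and 4.13 but did not pass. Cluster 20 (Ngp, Camp, Ltf, Prok2), which is part of this class, held 0.332% and 0.167% of the MI libraries and 2.14% and 1.58% of the MIKO libraries. Cluster 1 (Il23a, Icam1, Tnf) held 10.3% and 10.6% of MI and 21.8% and 21.6% of MIKO cells, while cluster 14 (Stfa1, Lcn2) held 10.1% and 4.66% and then 1.49% and 0.545%. Egln3, an oxygen sensor induced by hypoxia, stood at 112 ± 1.34 CPM in MI and 34.4 ± 5.46 CPM in MIKO without passing (edgeR adjusted p = 0.128). Summed haemoglobin RNA in these cells was 2.60 and 3.66 CPM in MI, and 3.66 and 505 CPM in MIKO. Cardiomyocyte RNA was 57.3 and 132 CPM in MI, and 600 and 182 CPM in MIKO.

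Of 11014 genes tested in this class, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called Prok2 alone (log2 3.77, SE 0.22, adjusted p = 0.0120), and 849 had an unadjusted p under 0.05. Camp (adjusted p = 0.197) and Ltf (0.128) missed the threshold of the same edgeR test. The count was 373 with no filter on low counts and 80 with DESeq2. With the replicate number as a block it was 0 (611 at an unadjusted p under 0.05), so the call of Prok2 was lost there.

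**Figure D4:**
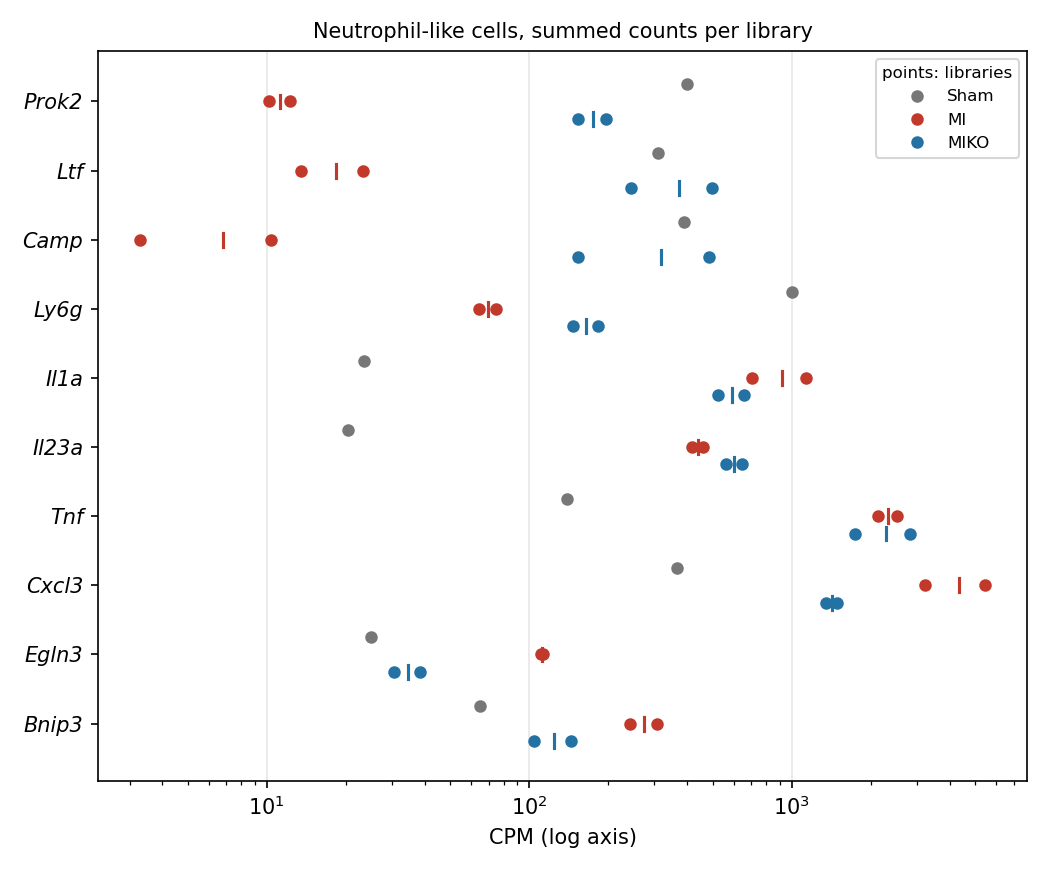
CPM of selected genes in neutrophil-like cells on a log axis, with 1 point per library and a tick at the mean of the 2 MI and the 2 MIKO libraries. Prok2 averaged 11.2 CPM in MI and 175 CPM in MIKO and lay at 400.2 CPM in Sham.

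Camera with a preset correlation called 21 of the 43 lists in MIKO against MI neutrophil-like cells, 6 higher and 15 lower. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05, lowest adjusted p = 0.543), and fry called 0 for direction (6 at an unadjusted p under 0.05) and 4 for change either way. No member of these lists passed edgeR's test over all genes. The glycolysis and hypoxia list had a median log2 difference of -0.75 (camera adjusted p = 2.11e-24; adjusted p = 0.543 with an estimated correlation). Of 28 genes 18 fell adjusted over the list alone, among them Egln3 (-1.89), the glycolytic enzyme gene Pfkl (-1.43), Bnip3 (-1.34) and the glucose transporter gene Slc2a1 (-0.93). The 13 mitochondrially encoded genes all rose adjusted over the list alone, with mt-Nd5 at 1.01 and mt-Nd1 at 0.94. Their median was 0.94 (camera adjusted p = 5.42e-16, or 0.543 with an estimated correlation). Their share of UMIs also served to filter barcodes, and a difference in cell quality was not tested as a cause. Type I interferon response genes had a median of -0.82 (camera adjusted p = 5.23e-12; adjusted p = 0.543 with an estimated correlation), with none of 37 past the test even adjusted over the list alone. This call was lost without MI replicate 1 (camera adjusted p = 0.177). Isg15 stood at 2165 and 1334 CPM in MI, and 733 and 1248 CPM in MIKO, and Zbp1 had a log2 difference of -1.54. The interferon-led cluster 12 held 8.45% and 2.46% of MI and 1.74% and 3.94% of MIKO cells. MHC class I genes had a median of -0.52 (camera adjusted p = 1.15e-08; adjusted p = 0.543 with an estimated correlation), with 8 of 18 lower adjusted over the list alone, such as H2-K1 (-0.63) and the immunoproteasome gene Psmb8 (-0.72).

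Cholesterol synthesis genes had a median log2 difference of 0.56 in the same neutrophil-like cells (camera adjusted p = 6.86e-06; adjusted p = 0.543 with an estimated correlation). Of 23, Cyp51 (1.76) rose adjusted over the list alone, and Idi1 stood at 1.86 and Insig1, which holds back cholesterol synthesis, at 0.85. Genes of tissue-activated neutrophils had a median of -0.35 (camera adjusted p = 6.86e-06; adjusted p = 0.543 with an estimated correlation). Of 24, 2 fell adjusted over the list alone, and members went both ways: Cxcl3 stood at -1.81, Cd274, which encodes PD-L1, at -1.17 and Ptgs2, the prostaglandin synthase gene, at 0.64. Granule genes had a median of 0.07 and a mean of 0.64 (camera adjusted p = 0.0102; adjusted p = 0.543 with an estimated correlation). Of 24, 6 rose and 1 fell adjusted over the list alone, among them Ly6g (1.04) and Anxa1 (0.91) beside Camp and Ltf. Cardiomyocyte genes had a median of 1.94 (camera adjusted p = 8.48e-11; adjusted p = 0.543 with an estimated correlation), with 10 of 15 higher adjusted over the list alone.

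T cell-like cells were few, with 657 in Sham, 109 and 216 in MI and 108 and 159 in MIKO. In MIKO against MI, Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), the main cytokine of type 17 T cells, fell from 90.5 ± 17.5 to 8.79 ± 7.15 CPM (SD, n = 2), or from 28 and 65 UMIs to 1 and 7, with 128 UMIs in Sham. Ube2c, which acts in mitosis, had 157 UMIs in Sham, 4 and 109 in MI and 0 and 3 in MIKO. Ccl12, a chemokine of macrophages, rose from 14.5 ± 8.63 to 80.1 ± 18.2 CPM, or from 3 and 13 UMIs to 18 and 47. Cd209a, a dendritic cell gene named after its values were seen, had 186 UMIs in Sham, none in either MI library, none in MIKO replicate 1 and 45 in MIKO replicate 2. Of 7093 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4, 2 higher and 2 lower: Il17a (log2 -3.27, SE 0.47, adjusted p = 0.00147), Ube2c (-4.76, 0.89, 0.0459), Ccl12 (2.25, 0.44, 0.0482) and Cd209a (adjusted p = 0.0482). DESeq2 called 0, with 89 at an unadjusted p under 0.05 against 466 with edgeR. The edgeR count was 67 without MI replicate 1, 20 without MI replicate 2, 36 without MIKO replicate 1, 23 without MIKO replicate 2, 42 with no filter on low counts and 1 with RLE size factors. Il17a was called in each of these edgeR fits. With doublets kept edgeR again called 4 genes, but of the first 4 only Il17a was among them: Ccl12 had a log2 difference of 1.01 (adjusted p = 0.451) and Ube2c had an adjusted p of 0.0825. Without MI replicate 2 Ube2c did not pass. Without MIKO replicate 2 only Il17a and Ube2c of the first 4 passed, and 3 of the 4 kept their direction.

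In MI against Sham, a few genes of antigen presentation and chemokines differed in the T cell-like sums. The MHC class II genes H2-Eb1 (log2 -2.98, SE 0.69) and H2-DMb1 (-3.06, SE 0.65) fell, as did the lectin gene Mgl2 (-6.24, SE 0.77), while the chemokine genes Cxcl3 (4.48, SE 0.79) and Ccl7 (2.06, SE 0.48) rose. These are genes of macrophages and dendritic cells: in monocyte/macrophage-like cells H2-Eb1 stood at 1993 CPM in Sham and 371 ± 127 CPM in MI, Mgl2 at 148 and 13.5 ± 3.12 CPM, and Cxcl3 at 129 and 968 ± 48.4 CPM (SD, n = 2). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 genes rose and 40 fell, with adjusted p = 3.81e-05 for Mgl2, 0.00494 for Cxcl3 and 0.0396 for Ccl7. DESeq2 called 0 (93 at an unadjusted p under 0.05, and 372 with edgeR). The edgeR count of 45 became 120 without MI replicate 2, 91 without MIKO replicate 1, 89 without MIKO replicate 2, 121 with no filter on low counts and 117 with doublets kept.

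In B cell-like cells, 268 to 1762 per library, a single gene was called in each comparison, the immunoglobulin light chain segment Igkv4-91, named after its values were seen. It stood at 18.01 CPM in Sham, 252 ± 20.2 CPM in MI and 36.8 ± 5.998 CPM in MIKO (SD, n = 2). It rose in MI against Sham (log2 3.83, SE 0.28, adjusted p = 0.00327) and fell in MIKO against MI (-2.83, SE 0.21, adjusted p = 0.00413) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Variable segments resemble one another and their counts can be split between copies, so this gene is uncertain. In MIKO against MI, the genes by the naming rule did not pass: Fosl2 stood at 1.31 and Dph5 at 1.06 on the log2 scale, the interferon-induced gene Isg15 at -1.19, the chemokine gene Ccl4 at -1.37 and the glycolytic gene Pgk1 at -0.83. Myl7, an atrial muscle gene, stood at 2.68. In MI against Sham, Stat4 (1.07), Mtmr2 (1.40), Spata5 (1.38), Klf2 (-1.57), which encodes a factor of resting lymphocytes, Rhob (-1.52) and Myl7 (-4.13) did not pass either. MIKO against MI had 333 of 8612 genes at an unadjusted p under 0.05, and MI against Sham had 334. With no filter on low counts edgeR called 70 and 119 genes, and DESeq2 called 2 and 6. For MIKO against MI edgeR called 2 without MI replicate 1, 7 without MI replicate 2, 88 without MIKO replicate 1 and 78 without MIKO replicate 2. For MI against Sham it called 4, 12, 113 and 112.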

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

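The tests in this part were chosen after the results were seen, except those that left out clusters 13 and 18 or cluster 20, whose bounds were set before their results.

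The clusters without a name entered no comparison of genes, and 4 of them lay above the Sham library beyond its interval in all libraries of a group. Cluster 8, led by the predicted gene Gm28592 and by AY036118 and Lars2, with a median of 1472 UMIs, made up 4.75% and 3.51% of the MI libraries and 0.963% of Sham. Its MIKO shares lay far apart, at 0.495% and 9.92%. Cluster 11, led by Neat1 and Malat1, with a median of 1191.5 UMIs, made up 2.63% and 4.73% of the MI libraries, 5.37% and 2.41% of the MIKO libraries and 1.36% of Sham. Cluster 28 was led by the atrial muscle genes Nppa, Myl7 and Sln, with 9 cardiomyocyte and 10 neutrophil markers raised. It made up 1.83% and 0.837% of the MIKO libraries and 0.549% of Sham. Cluster 32, led by AY036118 and Col1a1, made up 1.16% and 0.329% of the MIKO libraries and no Sham cell.

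Resident macrophage genes had a median log2 difference of 1.07 between MIKO and MI monocyte/macrophage-like cells, where 3 of 20 passed over all genes and the list was called with the preset correlation but not with an estimated one (adjusted p = 0.455). A mixture of Sham-like tissue into the MIKO samples, at the 77.7% that the summed and mostly abundant resident genes need, would bring 3.599% NK cell-like cells, and the MIKO libraries held 0.334% (95% interval 0.230 to 0.468) and 0.470% (0.349 to 0.619), which argues against it unless NK cells were lost as well. The Cell Ranger version of MIKO replicate 1 is argued against, narrowly, because 16 of 20 resident genes lay above both MI libraries in MIKO replicate 2 and the bound, set afterwards, was 15. What stays open is a larger share of the resident clusters 13 and 18, because without them the median log2 difference was 0.3658 (quartiles 0.0357 and 0.878) against 0.930 with them, both from the mean CPM of the groups with 1 added in place of the edgeR fit, between the bounds set, and those clusters are defined by the tested genes. More atrial tissue in the MIKO samples may also account for it, since cluster 28 was at least 6.941 times the higher MI library. That cluster had 10 neutrophil markers raised beside 9 cardiomyocyte markers, so whether CD45 selection should remove its droplets is not known. Its share is therefore no plain measure of atrial tissue. The ratio was also known when its bound was set, and Sham lay below both MIKO libraries with resident genes as high. Survival or renewal of resident macrophages without Pcsk9 was not tested.

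Prok2 was higher in MIKO than in MI neutrophil-like cells, and Camp and Ltf had large differences that did not pass. Without cluster 20 the log2 difference of the summed Prok2, Ltf, Camp, Ngp and Ly6g went from 2.40 to -2.39. A larger share of that cluster would give the loss of the rise, but not by itself the reversal. Outside the cluster the sums were 844 and 145.5 CPM in MI and 102 and 86.6 CPM in MIKO. The 5 genes are the cluster's own leading genes, MI replicate 1 kept 844 CPM outside it and Prok2 stayed higher without it (26.8 and 13.5 CPM in MIKO, 8.60 and 10.4 CPM in MI), so the test was judged, after its value was seen, to decide nothing. More blood left in the MIKO hearts could bring cells of that cluster. Haemoglobin RNA was 1.002 times the higher MI library in MIKO replicate 1, within the bound set against it. It was 138 times that library in MIKO replicate 2, and 1 library excludes nothing. An effect of the missing Pcsk9 on release of neutrophils from the marrow stays open and untested.

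The neutrophil gene S100a8 was higher in MIKO than in MI monocyte/macrophage-like cells, and S100a9 had a log2 difference of 2.35 without passing. In 0 of 4 other immune classes were both genes together higher in both MIKO libraries than in both MI libraries. In MIKO replicate 2 they summed to 879.5 CPM in monocyte/macrophage-like cells. The B, T, NK and dendritic cell-like sums were 291, 218, 127 and 90.8 CPM, under both MI libraries. This argues against free neutrophil RNA spread equally over the cells of that library. The sums in MIKO replicate 1 were 1483 CPM and then 690, 1336, 1612 and 595 CPM. The B and NK cell-like values lay above both MI libraries, so free RNA is not excluded there. For neutrophils of the average profile in shared droplets, 8 other neutrophil markers were looked at, picked afterwards. Their median log2 difference was 0.0323. At the 1.62% of neutrophil RNA that the rise of S100a8 needs, these markers would rise by 378 CPM in sum, and the observed difference was 7.499 CPM (SE 92.1). That test rests on the average neutrophil profile of these libraries. Its SE comes from 2 against 2 libraries and is itself uncertain. The shortfall thus speaks against shared droplets without excluding them. The neutrophil marker list fixed beforehand was called higher in these cells by camera with the preset correlation. This call was lost with doublets kept and at the finer clustering. At the finer clustering, a neutrophil-like cluster led by Saa3 and Lcn2 had 13 neutrophil and 8 monocyte/macrophage markers raised. It held 18 and 8 cells of the MI libraries and 109 and 75 of the MIKO libraries. Free neutrophil RNA in MIKO replicate 1, shared droplets and neutrophils with another profile thus stay open. So does expression in the macrophages or monocytes themselves, a hypothesis with no test here.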

How the results depend on the processing

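All alternatives were chosen before the data were examined, except the crossed pairing. Counts from edgeR are given unless a tool is named, and the cause of a change was not tested except where fewer libraries or cells make it plain. Single genes kept their direction and side of the threshold in 1539 of 1831 reruns, were weaker in 118, stronger in 172 and reversed in 2: Ldlr with doublets kept, at -0.0834 in T cell-like and -0.253 in B cell-like cells (MIKO against MI). These reruns pool both comparisons and include genes that did not pass to begin with. Of the 10 named genes past the threshold for MIKO against MI in any class, 2 stayed past it with doublets kept and 4 with no filter. The number was 7 with DESeq2, 8 with RLE factors and 9 with stricter cells, equal cells or resolution 2.0. Class shares kept their direction and side of the threshold in 142 of 183, were weaker in 31, stronger in 2 and reversed in 8. Reversed for MIKO against MI were neutrophil-like cells with TMM factors (0.0159) and without MI replicate 1 (0.212), dendritic cell-like without MI replicate 1 (-0.230), T cell-like (0.0540) and mural-like (0.112) without MI replicate 2, endothelial-like without MIKO replicate 1 (-0.238) and mural-like without MIKO replicate 2 (0.166). Leaving out 1 library gave ranges of -0.238 to 0.212 for neutrophil-like, -0.230 to 0.905 for dendritic cell-like, -0.630 to 0.0540 for T cell-like, -0.845 to 0.166 for mural-like and -0.238 to 1.199 for endothelial-like shares. For MI against Sham the dendritic cell-like share reversed with TMM factors (0.448).

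For MIKO against MI, the 10 genes of monocyte/macrophage-like cells became 0 with no filter (1376 at an unadjusted p under 0.05) or doublets kept (1394), 153 with DESeq2, 6 with stricter cells, 37 at resolution 2.0 and 0 to 442 without 1 library. Both counts of 0 without a library came from leaving out an MI library (1294 and 978 at an unadjusted p under 0.05), and 106 and 442 from leaving out MIKO replicate 1 or 2. The 1 gene of neutrophil-like cells became 373 with no filter, 80 with DESeq2, 4 with doublets kept, 4 at resolution 2.0, 2 with equal cells and 1 to 27 without 1 library (27 without MI replicate 1, 9 without MIKO replicate 1). The 4 genes of T cell-like cells became 1 with RLE factors, 42 with no filter, 0 with DESeq2 (89 at an unadjusted p under 0.05) and 20 to 67 without 1 library (67, 20, 36 and 23 without MI replicates 1 and 2 and MIKO replicates 1 and 2). The 1 gene of B cell-like cells became 70, then 2 with DESeq2, stricter cells or doublets kept, and 2 to 88 without 1 library (2, 7, 88 and 78). The 2 shares became 0 with stricter cells, TMM factors or resolution 2.0 (2, 2 and 3 at an unadjusted p under 0.05), 1 with doublets kept (fibroblast-like) or without stromal classes (NK cell-like), 2 with limma, and 0 to 1 without 1 library (0 without MI replicate 1, MI replicate 2 or MIKO replicate 1, with 1, 0 and 0 at an unadjusted p under 0.05).

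For MI against Sham, the 1279 genes became 385 with no filter and 52 to 2417 without 1 library (52 and 334 without MI replicates 1 and 2, 2394 and 2417 without MIKO replicates 1 and 2). The 304 became 1589 with no filter, 614 with DESeq2, 575 with doublets kept and 231 to 643 without 1 library (643 without MI replicate 2, 486 without MIKO replicate 1). The 45 became 121, 0 with DESeq2 (93 at an unadjusted p under 0.05), 117 with doublets kept, 29 with equal cells and 65 to 120 without 1 library (120, 91 and 89 without MI replicate 2 and MIKO replicates 1 and 2). The 1 gene of B cell-like cells became 119, 6, 12 with doublets kept and 4 to 113 without 1 library (4, 12, 113 and 112). The 7 shares became 0 without MI replicate 1 (4 at an unadjusted p under 0.05), 2 without MI replicate 2 and 7 without either MIKO library, with 7 by limma. Calls of gene lists became 0 with an estimated correlation in all 3 sets (5, 1 and 5 at an unadjusted p under 0.05) and 0 with fry for direction (7, 6 and 15), and fry for change either way gave 14, 4 and 29. Leaving out 1 library gave 19 to 26 and 19 to 24 lists for MIKO against MI and 22 to 26 for MI against Sham. The 1 UMI of Pcsk9 became 0 among the cells that passed the filters.

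Deviations of same-numbered MI and MIKO libraries correlated at -0.120, -0.330, -0.025 and -0.0986 in monocyte/macrophage-, neutrophil-, T cell- and B cell-like cells, so same-numbered libraries did not deviate together. With 2 libraries per group a negative value equals a positive one for the crossed numbers, so a crossed pairing is not excluded. With the replicate number as a block the counts went from 10 to 5, 1 (Prok2) to 0 (611 at an unadjusted p under 0.05), 4 to 5 and 1 to 0 (239), and the shares from 2 to 1, the NK cell-like share being lost (adjusted p = 0.0502). A crossed pairing, tried after seeing the data, called 45 genes in monocyte/macrophage-like and 119 in neutrophil-like cells.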

Other observations

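The comparisons in this part were chosen after the results were seen, and the lists they use were fixed before the data were examined.

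Some gene groups were not described above. In MI against Sham monocyte/macrophage-like cells, type I interferon response genes had a median log2 difference of 0.52 (camera adjusted p = 3.95e-08; adjusted p = 0.644 with an estimated correlation). Of 38, 5 rose, or 14 adjusted over the list alone. Mitochondrially encoded genes had a median of -0.65 (camera adjusted p = 5.92e-06; adjusted p = 0.558 with an estimated correlation), with 5 of 13 falling, or 6 adjusted over the list alone. Their medians in neutrophil-like cells were -1.29 in MI against Sham and 0.94 in MIKO against MI. For MI against Sham, camera gave an adjusted p of 3.78e-10, or 0.46 with an estimated correlation. There 6 of 13 fell, or 11 adjusted over the list alone. Over all deposited barcodes the median mitochondrial share was 1.27% in Sham, 0.436% and 0.597% in MI and 0.595% and 0.641% in MIKO. A difference in cell quality was not tested as a cause. Genes that respond to type II interferon were lower in MIKO than in MI, with medians of -0.30 in monocyte/macrophage-like cells (camera adjusted p = 3.96e-09; adjusted p = 0.508 with an estimated correlation) and -0.71 in neutrophil-like cells (camera adjusted p = 1.69e-07; adjusted p = 0.543 with an estimated correlation). None of the 25 genes in the former passed even adjusted over the list alone, and 1 of 21 in the latter fell adjusted over the list alone.

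In T cell-like cells, genes of the G2/M phase of the cell cycle had a median log2 difference of -3.58 in MIKO against MI (camera adjusted p = 4.47e-09; adjusted p = 0.627 with an estimated correlation). Of 18, Ube2c fell over all genes, and 15 fell adjusted over the list alone. MI replicate 1, with 4 Ube2c UMIs, lay nearer to the MIKO libraries than to MI replicate 2, with 109. Genes of T cell activation had a median of -0.44 (camera adjusted p = 2.57e-08; adjusted p = 0.543 with an estimated correlation), with 1 of 24, Il17a, falling over all genes and 5 adjusted over the list alone.

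The changes in MI against Sham were set against those in MIKO against MI. Both comparisons use the MI libraries, which alone gives a negative relation. In monocyte/macrophage-like cells r across genes, which are not independent replicates, was -0.520, against -0.378 in 20 simulations without any effect, and the covariance was -0.240 against -0.0534. In neutrophil-like cells r was -0.286, weaker than the -0.328 simulated, and the covariance was -0.211 against -0.121.

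To keep the comparisons apart, 1 MI library was then used for each, so that no library entered both log2 differences. Each fit still held Sham and both MIKO libraries. The spread therefore came from the MIKO libraries, also where genes were called as changed in MI against Sham. In monocyte/macrophage-like cells r was -0.226 with MI replicate 1 set against Sham and MI replicate 2 against MIKO, and -0.420 the other way round. The simulated means were -0.00370 and -0.00125, and the lowest simulated values were -0.0351 and -0.0188. Of the genes that changed in MI against Sham, 185 of 334 (55.4%) and 43 of 52 (82.7%) had the opposite sign in MIKO against MI. In neutrophil-like cells r was 0.0399 and -0.194, and 301 of 642 (46.9%) and 298 of 444 genes (67.1%) had the opposite sign. Over all genes the share with opposite signs was 51.0% and 60.02% in monocyte/macrophage-like cells and 44.5% and 50.5% in neutrophil-like cells, against 49.9% to 50.05% simulated. The relation was thus negative in both arrangements in monocyte/macrophage-like cells and in 1 of 2 in neutrophil-like cells, and its size depended on the MI library. No test compared the classes. The simulations treat genes as independent, so their spread is too narrow.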
